A study of Mus musculus with 9 samples.

How the data were processed

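RNA sequencing of retinal ganglion cells, the neurons whose axons form the optic nerve, was reanalysed from a deposited gene table of 9 libraries. Per the labels, the cells were sorted by flow cytometry from mouse retinas of 3 groups with 3 libraries each. The Ctrl group came from intact wild-type retinas. The ONC group came from wild-type retinas 3 days after optic nerve crush, an injury that severs the axons of these cells. The CKO group came from retinas 3 days after crush in mice lacking the zinc transporter ZnT3 (gene Slc30a3) in amacrine cells, the inhibitory interneurons that contact ganglion cells. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

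Per the labels' protocols, RNA was amplified to cDNA with a whole-transcriptome kit (Discover-sc WTA Kit V2) and libraries were made with a tagmentation kit (TruePrep DNA Library Prep Kit V2). The labels call the libraries stranded, but a tagmentation kit of this kind does not mark the strand, so reads of a gene and of an overlapping antisense gene could not be told apart. Per the submitters' processing notes, Trimmomatic 0.36 and the genome builds GRCm38 and mm10 were used. The aligner, the counting tool and the annotation were not given in the sources used here. Per the file headers, the deposited table held an expected count and an FPKM value (fragments scaled to gene length and depth) for each gene in each library. The expected count values were not normalized and were 68.3% to 73.1% whole numbers. The FPKM values were normalized by the authors for gene length and depth.

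The table had 24772 entries, of which 21970 were Ensembl genes and 2802 were loci assembled by the authors without a gene name. Gene symbols, positions, lengths and GC content were taken from GENCODE mouse release M21, which names genes on GRCm38, and 21956 Ensembl identifiers matched. The table had 18 value columns. The FPKM columns of ONC, 3 in number, could not be matched to single samples and were not used. The Ctrl and CKO columns carried replicate numbers 1 to 3, as in the labels. The ONC columns carried the numbers 3, 5 and 6 where the labels number the samples 1 to 3, so each was treated as an ONC library without a replicate number and is called column 3, 5 or 6 here. Total counts ranged from 14166996 to 25571715 per library. PCR copies were not marked by molecular identifiers, so counting limits cover counting error only.

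Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with edgeR's filterByExpr by group, which left 15841 genes, 1630 of them assembled loci. Libraries were scaled by the trimmed mean of M values (TMM). One quasi-likelihood model was fitted to all 9 libraries with no covariate, and ONC was compared with Ctrl, CKO with ONC, and CKO with Ctrl. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. Every adjusted p of a gene comes from this edgeR test unless another tool is named. Group values of genes are given as CPM, counts scaled to library size, on the TMM scale, as mean ± SD of 3 libraries, and log2 fold changes are given ± SE. Marker sums, the ranks and means over 9 libraries, and the limits for a count of 0 are CPM by library totals without TMM. With unchanged groups of 3 libraries, 10% of genes are expected to have groups that do not overlap.

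Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists tested within a comparison. There were 15 pathway lists: ganglion cell identity, axon injury and regeneration-associated genes, integrated stress response, apoptosis and p53, zinc handling, growth suppressors, neurotrophic and cytokine signalling, synaptic and ion channel genes, cholesterol biosynthesis, oxidative stress (Nrf2), interferon-stimulated genes, cytokines and chemokines, immediate early and dissociation genes, oxidative phosphorylation, and cytosolic ribosomal proteins. There were 13 cell type lists: amacrine cell, rod, cone, bipolar cell, horizontal cell, Müller glia, astrocyte, microglia and macrophage, endothelial cell, pericyte, retinal pigment epithelium, erythrocyte, and neutrophil and T cell. The erythrocyte list had too few tested members for a test. Camera was repeated with the correlation estimated from the data.

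Genes are named by a rule: in each comparison, the 8 largest rises and 8 largest falls among called genes whose libraries did not overlap between groups and whose mean reached 16 counts and 1 log2 CPM, the 3 members of each list with the lowest p, and 12 genes set in advance (Slc30a3, Mt1, Mt2, Mt3, Atf3, Jun, Sox11, Gap43, Ddit3, Rbpms, Pou4f1 and Nefl). The groups, comparisons, tests, lists, naming rule and a set of other analyses were fixed before the data were examined. The other analyses were DESeq2 1.42.0, other scalings, other expression filters, voom with quality weights, a minimum log2 fold change of 1, only the 6 libraries compared, a replicate block and leaving out each library. Analyses chosen after seeing the data were the sum of ONC columns 3 and 6 as 1 library, ONC column 5 alone, a per-library correction for GC content and length, limma on log2(FPKM + 1) of the Ctrl and CKO libraries, and an adjusted p under 0.1.

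The comparisons share libraries, so their overlap was set beside data simulated without the effect in question, in 10 draws each. The procedure was tested on simulated counts for 15841 genes with 100 genes changed 2-fold and 100 changed 4-fold. The share recovered was 51% and 82% for ONC against Ctrl, 50% and 85% for CKO against ONC, and 41% and 78% for CKO against Ctrl. False calls made up 2.92%, 3.57% and 5.56% of the calls in these comparisons. All simulated libraries were drawn independently and without a trend in GC content, unlike ONC columns 3 and 6, which resembled each other closely. The changed genes were drawn only from those above a minimum mean count. These rates may therefore not hold for the comparisons with ONC or for genes with low counts. Near-identical genes, such as the 2 alpha globins, class I histocompatibility genes and ribosomal protein genes with pseudogenes, may exchange reads, so their values are uncertain. Mitochondrially encoded genes were not analysed here. The FPKM analysis was first run on all 9 libraries and then limited to the 6 matched ones because of the column mapping, not because of its result.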

Results

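The series profiled gene expression in sorted retinal ganglion cells to ask how crush of the optic nerve changed them and how loss of ZnT3 from amacrine cells altered that response. ZnT3 loads zinc into synaptic vesicles. The table held 3 Ctrl, 3 ONC and 3 CKO libraries, and none from intact knockout retinas. Total counts were 21324560, 14166996 and 25571715 in Ctrl replicates 1, 2 and 3. They were 21579146, 21094249 and 21908527 in ONC columns 3, 5 and 6, and 22952815, 23549482 and 21861237 in CKO replicates 1, 2 and 3.

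The targeted gene, Slc30a3 (ENSMUSG00000029151, GRCm38 chromosome 5, 31086106 to 31108237, minus strand), was near the detection limit in every library. Slc30a3 had 2, 10 and 16 counts in Ctrl replicates 1, 2 and 3. It had 0, 1 and 0 counts in ONC columns 3, 5 and 6, and 1, 4 and 2 counts in CKO replicates 1, 2 and 3. A count of 0 allowed up to 0.139 CPM in column 3 and 0.137 CPM in column 6. Slc30a3 fell below the expression filter. Without a filter its log2 fold changes were -4.45 in ONC against Ctrl (edgeR adjusted p 0.0576), 2.39 in CKO against ONC (0.388) and -2.06 in CKO against Ctrl (0.431), so it was not called. The deletion was in amacrine cells, whose markers took 0.0193% to 0.0584% of the counts. With Slc30a3 this low, and at 7 counts in all in CKO against 1 in ONC, these counts do not check the genotype.

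Rod photoreceptor transcripts dominated all 9 libraries. Abundant genes included the rod genes Gngt1 at 19801 CPM and Pdc at 14864 CPM, each as the mean of 9 libraries. The 15 rod markers took 8.68% to 10.9% of the counts, and the ganglion cell identity list took 0.0126% to 0.0283%. Among genes of the identity list, Isl1 ranked 3583rd at 58.8 CPM, Nefl reached 23.0 CPM, Thy1 8.9 CPM, Rbpms 3.1 CPM, Slc17a6 2.9 CPM, Pou4f1 0.8 CPM and Pou4f2 0.3 CPM. Whether the RNA of these genes, Isl1 included, came from ganglion cells alone was not tested. Differences between groups therefore describe the sorted material as a whole, in which most marker signal came from genes of other retinal cells.

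**Figure D1:**
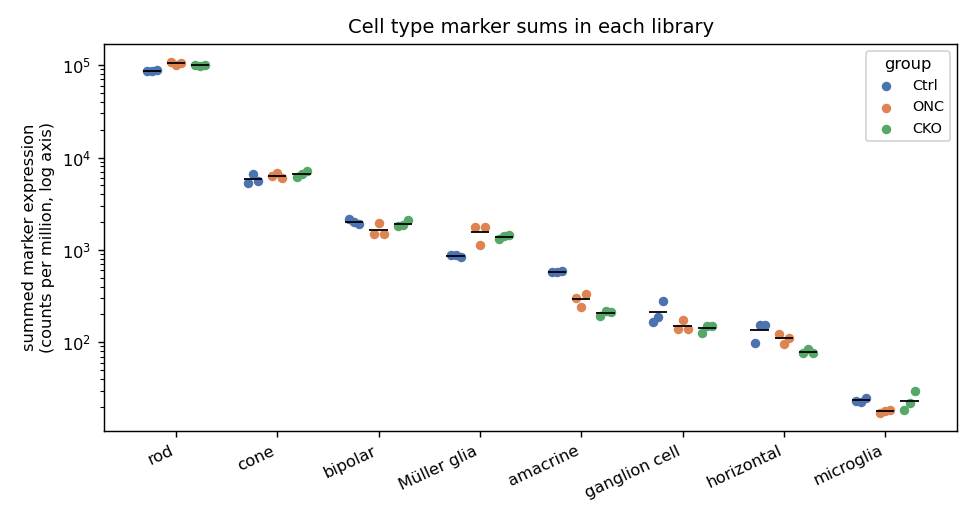
Summed expression of the marker genes of 8 retinal cell types (horizontal axis) in CPM on a log axis, with 1 point per library coloured by group and a bar at the group mean. Rod sums lay between 86836 and 109422 CPM and ganglion cell sums between 126 and 283 CPM.

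Libraries of a group varied alike in Ctrl and CKO but not in ONC. Between libraries of the same group, the variance over that expected from counting was 8.60 to 10.6 in Ctrl and CKO. ONC columns 3 and 6 differed by only 2.23 times the counting variance, against 0.984 for simulated random splits of 1 library. They were analysed as 2 libraries and, in another analysis, summed as 1. Their difference exceeded counting noise, which 2 preparations of the same cDNA would also show, so it does not make them independent. ONC column 5 correlated with the CKO libraries at r = 0.977 to 0.978, above its r of 0.949 with column 3 and 0.954 with column 6. With the Ctrl libraries, columns 3 and 6 correlated at r = 0.919 to 0.931 and column 5 at r = 0.960 to 0.963. These correlations are across genes, which are not independent replicates.

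**Figure D2:**
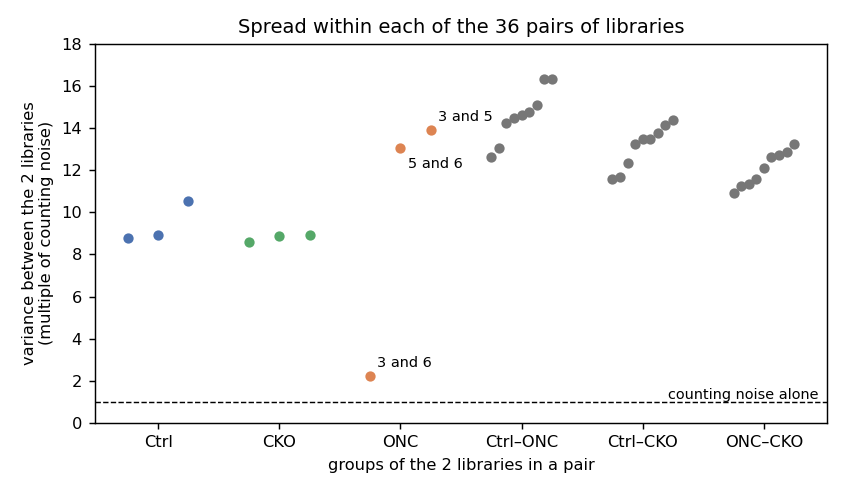
Variance between the 2 libraries of each of 36 pairs, as a multiple of counting noise (vertical axis), by the groups of the pair (horizontal axis). ONC columns 3 and 6 lay at 2.23, and the other 35 pairs lay between 8.60 and 16.3.

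ONC against Ctrl asked what crush changed in the sorted cells of wild-type mice by day 3. Injury-associated genes, interferon-stimulated genes and markers of rods and Müller glia were higher after crush. Genes of synapses and ion channels, amacrine cell markers, oxidative phosphorylation genes and ribosomal protein genes were lower. All these lists passed only at the preset correlation between genes. Of 15841 genes, 2057 were called higher and 2023 lower. The balance was 1221 higher and 718 lower with columns 3 and 6 summed, and 738 and 427 with column 5 alone. Groups did not overlap for 39.5% of all genes, where chance gives 10% with 3 independent ONC libraries and 20% with columns 3 and 6 taken as 1.

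The injury response included Stat3, which rose from 17.9 ± 3.88 to 58.6 ± 12.6 CPM (log2 fold change 1.71 ± 0.21, edgeR adjusted p 0.0011). Atf3 rose by 1.16 ± 0.22 (edgeR adjusted p 0.00512, but 0.126 with column 5 alone) and Tnfrsf12a by 1.02 ± 0.20 (edgeR adjusted p 0.00519) on the log2 scale. The axon injury list as a whole was higher (median 0.65, camera adjusted p 0.0162), with 7 of 22 tested members called higher and none lower over all genes, and also 7 adjusted over the list alone. That list did not pass with an estimated correlation (camera adjusted p 0.14), after GC correction (0.0567) or without ONC column 5 (median 0.26, camera adjusted p 0.104), and its median was 0.12 with column 5 alone. Jun (log2 fold change 0.39), Sox11 (1.62) and Gap43 (-0.58) were not called. Jun was at 23.5, 8.68 and 20.7 CPM in ONC columns 3, 5 and 6 and its log2 fold change was -0.60 with column 5 alone. Sox11 was at 0.438, 3.60 and 0.292 CPM in these columns and its log2 fold change was -0.28 without column 5. Fgf2 rose slightly, from 21.5 ± 0.931 to 30.2 ± 2.46 CPM. The opioid precursor gene Penk was listed at 0 in Ctrl and was at least 109-fold higher in ONC, taking 3 counts over the group as the floor. Penk reached 12.3 CPM in column 5 and 1.84 and 1.83 CPM in columns 3 and 6.

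Interferon-stimulated genes were higher (median 0.87, camera adjusted p 0.00117, but 0.111 with an estimated correlation and 0.131 with the stricter expression filter). Ifit1 rose by 3.28 ± 0.61 and Ifi27 by 1.60 ± 0.35 on the log2 scale, H2-D1 by 1.13 ± 0.21 (edgeR adjusted p 0.113 with column 5 alone), and 3 of 22 members were called, also 3 adjusted over the list alone. The immunoproteasome gene Psmb8 rose by 3.11 ± 0.64 (edgeR adjusted p 0.00688). The other large rises were Smim3, Cyb561a3, Scrn2, Anxa2 and Arhgdia, of which Smim3, Cyb561a3 and Scrn2 were not called with column 5 alone (edgeR adjusted p 0.164, 0.0569 and 0.196). Arhgdia (ENSMUSG00000025132, GRCm38 chromosome 11, 120578104 to 120581624) rose from 8.32 ± 2.51 to 69.5 ± 17.8 CPM (log2 fold change 3.05 ± 0.26, edgeR adjusted p 0.000255).

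Neuronal signalling genes were lower in the sorted material after crush. Amacrine cell markers summed to a mean of 579 CPM in Ctrl and 292 CPM in ONC. Less amacrine RNA in the sort therefore cannot be told apart from lower expression per cell. The synaptic and ion channel list had a median of -0.79 (camera adjusted p 0.00167, but 0.14 with an estimated correlation), with 16 of 38 members called lower and 2 higher over all genes, and 19 lower and 3 higher adjusted over the list alone. The AMPA receptor gene Gria2 fell by 1.16 on the log2 scale, from a mean of 165 to 73.7 CPM. The GABA receptor gene Gabra2 fell by 1.98. The largest falls were Vwc2, Rgs13, Gng8, Arhgap15, Rasgrp1, Olfm3, Fgf1 and Calb1, with log2 fold changes from -6.14 to -3.70. Olfm3 went from 24.5 ± 2.05 to 1.57 ± 0.389 CPM (edgeR adjusted p 0.000145).

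Markers of several retinal cells moved with crush, in opposite directions. Amacrine cell markers were lower (median -1.26, camera adjusted p 0.00256, but 0.14 with an estimated correlation), with Gad1 falling from 141 ± 7.03 to 43.3 ± 7.27 CPM and Tfap2b from 148 ± 6.01 to 62.0 ± 8.58 CPM. Rod markers were higher (median 0.42, camera adjusted p 0.00117, but 0.179 with an estimated correlation). The rod arrestin gene Sag rose from 5519 ± 318 to 14382 ± 1053 CPM (log2 fold change 1.38 ± 0.09, edgeR adjusted p 2.0e-05), while the rod genes Gngt1 and Pdc fell by 0.50 and fell by 0.79. The cone arrestin gene Arr3 rose from 242 ± 24.3 to 810 ± 53.5 CPM, although the cone list did not pass (camera adjusted p 0.177). Müller glia markers were higher (median 0.69, camera adjusted p 0.000102, but 0.111 with an estimated correlation), led by Crym, which rose from 11.8 ± 4.60 to 56.5 ± 8.19 CPM. The pigment epithelium gene Dct fell by 1.71, from 433 ± 89.0 to 132 ± 43.6 CPM (edgeR adjusted p 0.0013), and held in all 21 other analyses, but the other tested member, Rgr, was not called and the list did not pass. Of genes on the ganglion cell identity list, Chrnb3 fell by 1.86 (edgeR adjusted p 0.00135) and Isl1 by 0.51 (edgeR adjusted p 0.0334), while Tubb3 rose by 0.97 (edgeR adjusted p 0.049). The calls of Isl1 and Tubb3 held in 9 and 10 of 21 other analyses. The identity list did not pass (median -0.51, camera adjusted p 0.177). The axon injury, synaptic, amacrine, rod, interferon, Müller glia, oxidative phosphorylation and ribosomal lists passed at the preset correlation, and 0 lists passed with an estimated one.

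Zinc-related genes rose singly. The metallothionein gene Mt2 rose from 11.9 ± 1.82 to 31.7 ± 3.51 CPM (log2 fold change 1.42 ± 0.19, edgeR adjusted p 0.00135) and held in all 21 other analyses. Mt3 rose by 0.80 ± 0.23 but held its call in only 13 of 21, with an edgeR adjusted p of 0.0646 with columns 3 and 6 summed and 0.194 with column 5 alone. The zinc importer genes Slc39a7 and Slc39a1 rose by 1.31 ± 0.24 and 1.18 ± 0.22, with edgeR adjusted p of 0.115 and 0.0823 with column 5 alone. Mt1 was not called (log2 fold change 0.42), but its log2 fold change went from 0.002 to 1.05 over the other analyses, the highest with column 5 alone. The zinc handling list did not pass (camera adjusted p 0.157), with 6 of 23 members called higher over all genes and 6 adjusted over the list alone. Oxidative phosphorylation genes were lower as a list (median -0.36, camera adjusted p 0.00117, but 0.587 with an estimated correlation), with 27 of 75 members called lower and 5 higher. The 5 included Uqcrc1, Ndufv1 and Atp5b. The oxidative phosphorylation list did not pass after GC correction (median -0.13, camera adjusted p 0.0567) or with column 5 alone (median -0.04, camera adjusted p 0.624). Ribosomal protein genes had a median of -0.21 (camera adjusted p 0.00766, but 0.609 with an estimated correlation), with 25 of 76 members called lower and 3 higher. The ribosomal list did not pass after GC correction (median -0.07, camera adjusted p 0.0953) or without Ctrl replicate 3 (0.212), ONC column 5 (0.0648) or ONC column 6 (0.118). Its median was -0.12 with column 5 alone, and it passed in 12 of 19 other analyses.

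CKO against ONC asked what loss of ZnT3 in amacrine cells changed in crushed retinas. The growth factor gene Fgf2 was higher and Arhgdia lower in CKO, and both kept their calls in all 21 other analyses. Other calls, which included Cntf, Nupr1, Gfap and Tfap2b, depended on the settings and on single libraries of all 3 groups. edgeR called 93 genes higher and 44 lower, and 26.2% of all genes had groups that did not overlap, where chance gives 10%, or 20% with columns 3 and 6 taken as 1. Summing columns 3 and 6 left 2 calls, Fgf2 and Arhgdia, with 2552 genes at an unadjusted p under 0.05, and DESeq2 called 2261 genes.

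Fgf2 (ENSMUSG00000037225, GRCm38 chromosome 3, 37348346 to 37410108) was at 91.9 ± 1.67 CPM in CKO and 30.2 ± 2.46 CPM in ONC (log2 fold change 1.61 ± 0.13, edgeR adjusted p 0.000621). Its adjusted p was 0.00625 with columns 3 and 6 summed and 0.0111 with column 5 alone, where ONC is 1 library and the spread comes only from Ctrl and CKO. Arhgdia was at 9.67 ± 0.972 CPM in CKO, near its 8.32 CPM in Ctrl, and at 82.3, 49.1 and 77.0 CPM in ONC columns 3, 5 and 6 (log2 fold change -2.84 ± 0.26, edgeR adjusted p 0.00142).

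The cytokine gene Cntf was at 19.8 ± 2.98 CPM in CKO, 5.76 ± 0.885 in ONC and 5.38 ± 0.829 in Ctrl (log2 fold change 1.78 ± 0.24, edgeR adjusted p 0.0152). The stress gene Nupr1 was at 82.4 ± 5.63 CPM in CKO and 28.5 ± 5.72 in ONC (log2 fold change 1.53 ± 0.19, edgeR adjusted p 0.0141). The amacrine transcription factor gene Tfap2b was at 29.7 ± 1.88 CPM in CKO and 62.0 ± 8.58 in ONC (log2 fold change -1.06 ± 0.14, edgeR adjusted p 0.0141). Each of Cntf, Nupr1 and Tfap2b held its call in 13 of 21 other analyses, with edgeR adjusted p of 0.11, 0.0764 and 0.0697 when columns 3 and 6 were summed. The glial gene Gfap was at 7.21 ± 0.408 CPM in CKO, 2.01 ± 0.186 in ONC and 0.294 ± 0.119 in Ctrl, and held its call in 9 of 20 other analyses.

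The other large rises in CKO were Rgs13, Arhgap15, Gpr158, Ccdc38 and Triqk, which were all lower in ONC than in Ctrl. The other large falls were Caln1, Epb41l4a, Syt7, Syn2, Smg9, Sema4g and Rel. These genes held their calls in 8 to 10 of 20 or 21 other analyses. Epb41l4a went from 4.06 ± 0.387 CPM in ONC to 0.555 ± 0.327 in CKO (log2 fold change -2.86 ± 0.44). Mt2 was higher in CKO at 56.4 ± 10.3 CPM but was not called (log2 fold change 0.83 ± 0.18, edgeR adjusted p 0.0512), and Mt1 was not called either (0.72 ± 0.26, edgeR adjusted p 0.107). The log2 fold change of Mt1 was 0.11 with column 5 alone and reached 1.13 in other analyses. Atf3, Jun, Sox11, Gap43, Ddit3, Rbpms, Pou4f1, Nefl and Mt3 were not called. The zinc handling list (camera adjusted p 0.501) and the axon injury list (camera adjusted p 0.346) did not pass.

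Energy and translation genes were higher in CKO than in ONC as lists. The oxidative phosphorylation list had a median of 0.27 (camera adjusted p 3.78e-06) and the ribosomal protein list 0.14 (camera adjusted p 0.0212), but 0 of 75 and 0 of 76 members were called over all genes, and 0 and 4 adjusted over each list alone. Neither list passed with an estimated correlation, and the ribosomal list passed in only 6 of 19 other analyses. With column 5 alone the oxidative phosphorylation median was -0.04. After correction for GC content and length its median was 0.11 (camera adjusted p 0.214) and the ribosomal median was -0.06 (camera adjusted p 0.748), so neither list passed. No cell type list passed, Müller glia (median 0.12) and amacrine cell (median -0.28) included.

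**Figure D3:**
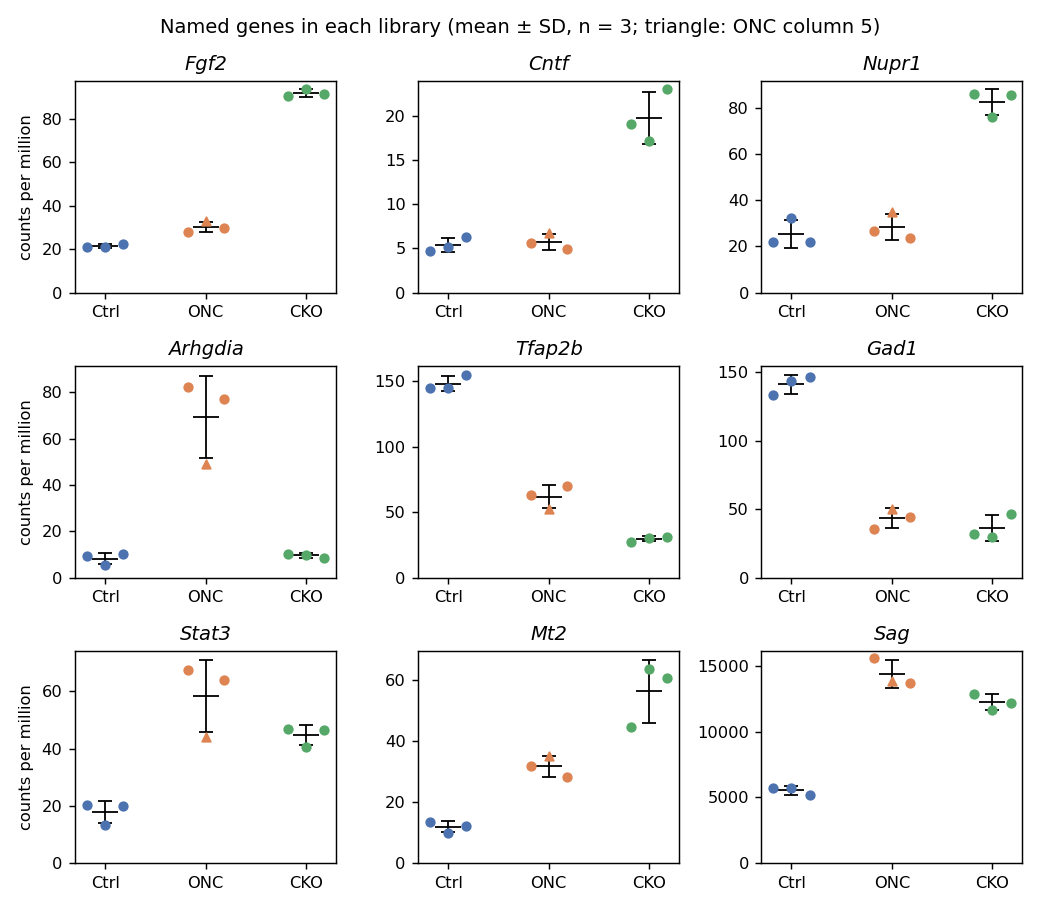
Expression of 9 named genes in CPM (vertical axes) by group (horizontal axis), with 1 point per library, a bar for mean ± SD of 3 libraries and a triangle for ONC column 5. Fgf2 lay at 90.5 to 93.8 CPM in CKO and at 27.9 to 32.8 CPM in ONC.

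CKO against Ctrl asked how cells from crushed knockout retinas differed from those of intact wild-type retinas. Crush and genotype differ at once in this comparison and cannot be separated. Injury genes, interferon-stimulated genes, antioxidant genes, Mt1 and Mt2 were higher in CKO, together with markers of Müller glia, rods and cones. Synaptic genes, ganglion cell identity genes and markers of amacrine and horizontal cells were lower. The Nrf2, identity, rod, cone and horizontal cell lists did not pass with an estimated correlation (camera adjusted p 0.0676, 0.172, 0.127, 0.217 and 0.159). edgeR called 684 genes higher and 725 lower, and with library totals only 538 higher and 909 lower. At a log2 fold change of at least 1, 220 were higher and 438 lower, and 35.7% of all genes had groups that did not overlap, where 10% is given by chance.

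The highest confidence calls included Fgf2, which was 2.10 ± 0.13 higher on the log2 scale (edgeR adjusted p 2.04e-05), and Tfap2b, which fell by 2.32 (edgeR adjusted p 2.04e-05). Mt2 rose by 2.25 ± 0.19 (edgeR adjusted p 0.000118) and Mt1 by 1.14 ± 0.26 (edgeR adjusted p 0.02), and the zinc handling list passed (median 0.25, camera adjusted p 0.00665, but 0.0676 with an estimated correlation). Mt3 was not called (0.57, edgeR adjusted p 0.154). The zinc handling list had 2 of 23 members called over all genes and 3 adjusted over the list alone. Gfap rose by 4.63 ± 0.43, Crym by 3.20 ± 0.26 and Ifit1 by 3.50 ± 0.62. Sprr1a, an injury gene, was listed at 0 in Ctrl and was at least 338-fold higher in CKO against 3 counts over the group, but its CKO values were 1.01, 0.355 and 48.2 CPM. Without CKO replicate 3 the edgeR adjusted p of Sprr1a was 0.177. Other large rises were Bcl3, Anxa2, Tagln2 and Smim3.

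The axon injury list was higher (median 0.63, camera adjusted p 5.39e-05), with Stat3, Cebpd and Atf3 up by 1.32 ± 0.21, 2.22 ± 0.38 and 1.14 ± 0.22. Gap43 went the other way and fell by 0.82 (edgeR adjusted p 0.0442), a call that held in 16 of 23 other analyses. Interferon-stimulated genes had a median of 1.12 (camera adjusted p 5.12e-07), with Irf9 among the members called. The Nrf2 list had a median of 0.36 (camera adjusted p 0.000165, but 0.0676 with an estimated correlation), led by Prdx6, which rose by 1.44 ± 0.13, and Cat, which rose by 1.29 ± 0.21. Synaptic genes had a median of -0.82 (camera adjusted p 5.12e-07), and Gria2, Gria4 and Gabra2 were lower. Here too, less amacrine RNA cannot be told apart from lower expression per cell. The largest falls were Vip, Gabra3, Epb41l4a, Cbln2, Olfm3, Greb1l, Caln1 and Calb1. Amacrine (median -1.33) and horizontal cell markers (median -1.06) were lower, and Müller glia (median 0.93), rod (median 0.43) and cone markers (median 0.32) were higher. The ganglion cell identity list was lower (median -0.82, camera adjusted p 0.0136, but 0.172 with an estimated correlation and 0.0939 without Ctrl replicate 3), with Chrnb3 and Rbfox3 called and Rbpms not (edgeR adjusted p 0.0547). With an estimated correlation the axon injury, synaptic, interferon, amacrine and Müller glia lists passed, and the identity, zinc, Nrf2, rod, cone and horizontal cell lists did not.

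The 2 comparisons with Ctrl shared many calls. There were 519 genes higher in both and 528 lower in both, against 88.8 and 92.6 for independent lists, and 2 genes were called in opposite directions. Their log2 fold changes had a covariance of 0.521 and a correlation of 0.574. Simulated data without effects, which also shared the Ctrl libraries, gave 0.123 and 0.5. With CKO simulated equal to ONC they were 1.04 and 0.894, or 1.03 and 0.863 with columns 3 and 6 sharing 1 draw. That simulation called 3748 genes in both comparisons on average, or 4129 with the shared draw, against 1049 here. It took the observed ONC and Ctrl means as true, which favours a large overlap. Part of the excess of shared calls over independent lists may come from the shared Ctrl libraries, which were too few to split. Shared genes included Stat3, Atf3, Ifit1, Anxa2, Crym, Gfap, Mt2, Sag and Arr3 among the rises and Olfm3, Calb1, Gad1, Gria2 and Chrnb3 among the falls.

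The position of CKO between Ctrl and ONC was examined next. No intact knockout libraries were in the series, so the crush response of knockout cells itself could not be measured. An altered response cannot be told apart from a difference between knockout and wild-type mice that was there before crush. Of the 4080 genes called in ONC against Ctrl, 3566 (87.4%) had a CKO mean on the Ctrl side of the ONC mean. This share was 61.0% when simulated with CKO equal to ONC, and 64.8% when columns 3 and 6 also shared 1 draw. The simulations drew genes independently and held no library-wide trend with GC content and length, which columns 3 and 6 carried. They therefore cannot say what share such a trend would give. After GC correction the share was 83.6%, and no simulation was run for that setting. Over the 1049 genes also called in CKO against Ctrl the share was 54.3%, a choice of genes that favours CKO far from Ctrl and was not simulated. The covariance of the ONC against Ctrl and CKO against ONC changes was -0.61, against -0.12 and -0.21 in the simulations. It moved with the analysis, from -0.21 with the stricter filter to -1.51 without a filter, -1.68 without ONC column 5 and -2.21 with column 5 alone, and no simulation was run for these. Arhgdia, Rgs13 and Arhgap15 lay close to Ctrl in CKO, whereas Fgf2, Gfap and Tfap2b lay farther from Ctrl in CKO than in ONC. Of the 137 genes called between CKO and ONC, 100 were also called in ONC against Ctrl, and 88 of these had CKO on the Ctrl side. Both calls use the same ONC libraries, which favours this side, and no simulated value was computed for these genes.

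**Figure D4:**
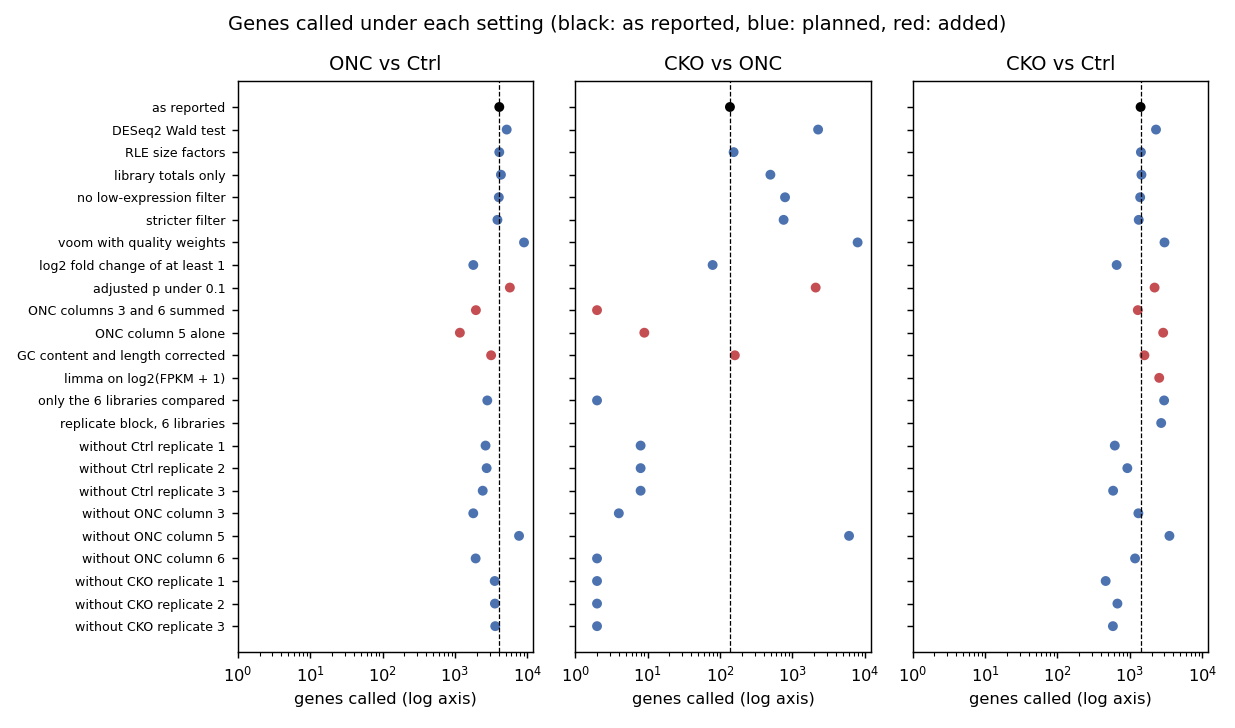
Number of genes called (log axis) in the 3 comparisons under each setting (vertical axis), with the reported setting in black, analyses set before the data were examined in blue and those added afterwards in red. Calls between CKO and ONC ranged from 2 to 7945.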

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

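The sum of ONC columns 3 and 6, ONC column 5 alone, the GC content and length correction, limma on FPKM and the adjusted p under 0.1 were chosen only after the results were seen. For CKO against ONC, the 137 calls became 2261 with DESeq2, 496 with library totals only (210 higher, 286 lower), 790 without an expression filter and 755 with a stricter one. They became 7945 with voom and quality weights, 79 at a log2 fold change of at least 1, 2093 at an adjusted p under 0.1, 2 with columns 3 and 6 summed, 9 with column 5 alone and 2 with only the 6 libraries compared. Scaling by relative log expression gave 154 and the GC correction 160. For ONC against Ctrl, the 4080 calls became 8955 with voom, 1785 at a log2 fold change of at least 1, 1939 with columns 3 and 6 summed and 1165 with column 5 alone. For CKO against Ctrl, the 1409 calls became 2300 with DESeq2, 3012 with voom, 658 at a log2 fold change of at least 1, 2198 at an adjusted p under 0.1, 2889 with column 5 alone, 2976 with only the 6 libraries compared and 2547 with limma on FPKM of these 6 libraries, which changed the method and the libraries at once. The cause was not tested, except that a fold minimum, a looser adjusted p and fewer libraries change the calls by their construction.

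Leaving out 1 library moved counts as follows. For ONC against Ctrl, calls were 2634 without Ctrl replicate 1, 2728 without Ctrl replicate 2, 2408 without Ctrl replicate 3, 1783 without ONC column 3, 7644 without ONC column 5 and 1923 without ONC column 6. For CKO against ONC, they were 8 without Ctrl replicate 1, 8 without Ctrl replicate 2, 8 without Ctrl replicate 3, 4 without ONC column 3, 6049 without ONC column 5, 2 without ONC column 6, and 2 without CKO replicate 1, 2 without CKO replicate 2 and 2 without CKO replicate 3. For CKO against Ctrl, they were 620 without Ctrl replicate 1, 924 without Ctrl replicate 2, 588 without Ctrl replicate 3, 3524 without ONC column 5, 464 without CKO replicate 1, 674 without CKO replicate 2 and 584 without CKO replicate 3. The cause was not tested.

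Pathway lists passing were 5, 2 and 6 and cell type lists 3, 0 and 5 in the comparisons ONC against Ctrl, CKO against ONC and CKO against Ctrl. With an estimated correlation, pathway lists passing were 0, 0 and 3 and cell type lists 0, 0 and 2. For ONC against Ctrl, 2 pathway lists passed after GC correction, and 5 cell type lists passed without an expression filter and 5 with column 5 alone. For CKO against ONC, 1 pathway list passed with library totals only, 1 without a filter, 1 with the stricter filter and 1 with columns 3 and 6 summed, and 0 with column 5 alone and 0 after GC correction. There, 1 cell type list passed without a filter and 1 with voom. Leaving out 1 library gave 4 to 6, 1 to 2 and 5 to 7 pathway lists and 3 to 5, 0 to 1 and 5 to 6 cell type lists.

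Some results turned direction, and the cause was not tested. With column 5 alone the oxidative phosphorylation median was -0.0365 in CKO against ONC. In ONC against Ctrl it was -0.0355, the same sign as its reported median of -0.36, but the direction given by camera turned. After GC correction, Ddit3 went from -0.42 to 0.0548 and Rps27l from -0.81 to 0.185 in ONC against Ctrl, and the ribosomal protein median was -0.0632 in CKO against ONC. The share of crush genes with CKO on the Ctrl side, 87.4%, was 54.3% over genes called also in CKO against Ctrl, 74.0% over all genes, 89.8% with voom, 83.4% with columns 3 and 6 summed, 76.8% with column 5 alone and 83.6% after GC correction. It ranged from 82.5% without ONC column 3 to 92.5% without ONC column 5. For the 74.0% over all genes, the simulations gave 66.8% with no effect in any group and 56.3% with CKO equal to ONC. With columns 3 and 6 sharing 1 draw they gave 71.25% and 58.45%. The 54.3% was not simulated. The replicate block gave 2711 calls in CKO against Ctrl, and libraries with the same number did not pair (correlations -0.024, 0.0156 and 0.0152); the ONC columns carry no such number.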

Other observations

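Several lists did not pass in any comparison. The integrated stress response list had medians of 0.14, -0.08 and -0.07 in ONC against Ctrl, CKO against ONC and CKO against Ctrl. In ONC against Ctrl 2 of its 20 members were called higher, Atf4 included, and 1 lower. The lower one was Ddit3 (log2 fold change -0.42, edgeR adjusted p 0.0355), a call that held in 7 of 21 other analyses. The apoptosis and p53 list (medians 0.28, -0.32 and -0.00165), growth suppressors (0.22, -0.01 and 0.08), neurotrophic and cytokine signalling (-0.14, 0.26 and 0.02) and cholesterol biosynthesis (-0.19, -0.04 and -0.04) did not pass, nor did cytokines and chemokines (0.37, 0.55 and 1.04) or immediate early and dissociation genes (0.54, -0.17 and 0.12). Bipolar cell (-0.26, 0.33 and 0.01), astrocyte (0.60, 0.08 and 0.53), microglia and macrophage (-1.56, 1.23 and 0.05), endothelial cell (0.34, -0.59 and -0.15), pericyte (-1.08, 0.39 and -0.49), retinal pigment epithelium (-0.77, 0.12 and -0.65), and neutrophil and T cell lists (-1.38, 0.93 and -0.46) did not pass either. Of 18 tested immediate early and dissociation genes, 7 were called higher and 3 lower in ONC against Ctrl. That list passed there without ONC column 5 (camera adjusted p 0.0468). Its sum was 945 and 932 CPM in ONC columns 3 and 6 and 685 CPM in column 5. It was 563 to 631 CPM in Ctrl and 630 to 713 CPM in CKO.

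Of the tests below, these were chosen only after the result was seen: the number of calls and the position over genes apart in CKO for the mislabel question, the rank of rod markers, the sum of ONC columns 3 and 6, and the bound for Müller glia, which replaced a bound that left the question open. The GC correction itself was also an analysis added after seeing the data. The 6 libraries of each comparison split 3 against 3 in 10 ways, too few for a share under 0.05. In ONC against Ctrl 1 of 10 splits reached the real 4080 calls, and the highest other split gave 0. In CKO against ONC 1 of 10 reached 137, and the highest other gave 1. In CKO against Ctrl 1 of 10 reached 1409, and the highest other gave 0.

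ONC columns 3 and 6 lay near each other and away from column 5. Only 6 genes had at least 30 counts in one of these columns and 0 in the other, against 34 to 136 in other pairs, which fits one amplified cDNA behind both columns. A trend with GC content and transcript length took 0.166 of the variance between column 5 and another ONC column. Within Ctrl and CKO it took at most 0.0098. These are shares of all the variance of a pair, the ordinary spread between libraries included. They therefore cannot say how much of the separation of column 5 came from the trend. The trend lay in columns 3 and 6, which were at 0.140 to 0.198 against Ctrl libraries and 0.150 to 0.216 against CKO libraries. Column 5 was at 0.0201 to 0.0324 against Ctrl and 0.00097 to 0.00625 against CKO. The trend thus ran through both comparisons with ONC. Whether column 5 is a mislabelled CKO library was tried in 3 tests: 0 genes called as the lowest number of calls (CKO libraries 0 to 3), where 1 library against 2 can call so few genes that the count decides nothing, and a position of 0.241 over genes apart in CKO (CKO libraries 0.0366 to 0.154), which leaves it open, and a position of 0.121 over the CKO against ONC calls (CKO libraries -0.0236 to 0.137), the test predicted beforehand, fits. The genes of that last test were picked for differing between CKO and columns 3 and 6. A true ONC library that lacked deviations private to columns 3 and 6 would also lie near CKO on them, so that test cannot decide. In values chosen after they were seen, Fgf2 (32.8 CPM), Cntf (6.71 CPM) and Arhgdia (49.1 CPM) in column 5 lay with ONC. These genes were called with column 5 counted as ONC and named because the groups did not overlap. Their side was set by that choice, and the question stays open.

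Rod transcripts lay far above ganglion cell transcripts. All 15 rod markers exceeded every gene of the ganglion cell identity list. The lowest rod marker, Nr2e3, was at 584 CPM and the highest gene of that list, Isl1, at 58.8 CPM. RNA of rods and other retinal cells in the sort stays an open explanation, since this rank of 15 markers restates the pattern and is no test of it, and no biological explanation was tested.

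The calls between CKO and ONC were few and depended on the analysis. With columns 3 and 6 summed 1.46% held, and all 137 directions were kept. The median log2 fold was then 1.02 against 1.09 and the median SE 0.21 against 0.181. Leaving out 1 Ctrl or CKO library left 1.46% to 5.84%. The calls lay close to the cutoff, with a median edgeR adjusted p of 0.0427. The share held therefore cannot decide what counting these columns as 2 independent libraries did. Genes at an unadjusted edgeR p under 0.05 fell from 4314 to 2552 with the columns summed. They were 4246 to 4256 without 1 Ctrl library and 3215 to 3788 without 1 CKO library. After correction for GC content and length 71 of the 127 calls with a value held, 55.9% (interval 46.8% to 64.7%), with a median log2 fold of 0.76, so a trend of this kind stays open. Only 0.730% of the calls lay near Slc30a3, against 0.997% of tested genes, so strain variants around the targeted gene do not explain them. The Müller glia list had a median of 0.124 (SD of members 0.386, highest 0.93), below the median of 1.09 for the 93 genes called higher. Those genes were picked for being called, which raises their median, and the bound was set after the result was seen. The comparison therefore cannot decide whether more Müller glia RNA in CKO was the whole cause. A changed state of these cells also stays open and was not tested.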
